A study of Homo sapiens with 12 samples.

How the data were processed

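RNA of T47D cells, a luminal breast cancer line that carries the progesterone and estrogen receptors, was measured by RNA-seq in 12 libraries. Cells received a control siRNA (siCT) or an siRNA against PRMT1 (siPRMT1) and then 10 nM of the synthetic progestin R5020, or its ethanol vehicle, for 6 h. Per the labels' protocols, RNA was extracted with TRIzol, libraries were made with the Lexogen SENSE mRNA kit, and each of the 4 groups holds 3 biological replicates. Each sample was placed in its group from its siRNA and treatment labels.

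The authors deposited, for each sample, a table of read counts per gene symbol, with whole-number values for 55765 genes and no normalization. Per the submitters' processing notes, Bowtie2 2.3.2.2, HTSeq 0.9.1 and DESeq2 (version not given in the sources used here) and the genome build hg19 were used. The notes give no role or order for these tools, and the aligner settings, the annotation release, the strand setting and the treatment of duplicate reads are not given in the sources used here. An aligner that does not cross introns, or a counter that passes over reads shared by several genes, lowers the counts of some genes in all libraries alike. Without a stated strand setting, reads of an antisense gene and of its partner cannot be told apart, and near-identical genes such as HSPA1A and HSPA1B can share or lose reads. Counting intervals and floors given here cover counting error only, since the counts carry no molecular identifiers. Bootstrap intervals resample genes and measure no spread between libraries.

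The authors also deposited a table of their own comparisons, with a log2 fold change, a Wald score, a p-value and an adjusted p-value for each gene in 4 comparisons. Its columns of means and spreads were not used here. The deposited log2 fold changes were taken as the second group over the first named in the file header, which was checked against the counts. The table was used only to compare its calls with those made here.

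Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with too few counts for the group sizes were removed with filterByExpr, which left 17727 genes, and library sizes were scaled by TMM. One mean per group was fitted over all 12 libraries, so that the groups share one estimate of the spread. Each comparison was tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. The comparisons were R5020 against ethanol in siCT cells and in siPRMT1 cells, siPRMT1 against siCT in ethanol and in R5020, the interaction (the R5020 effect in siPRMT1 cells minus that in siCT cells), and the average of both R5020 effects. Levels are CPM (edgeR's cpm function) after TMM scaling, with the SD over 3 libraries, and fold changes carry the standard error (SE) of the log2 value. P-values measure the spread between these libraries, which are biological replicates per the labels.

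A total of 25 gene lists were fixed before the data were examined. They hold progestin targets, estrogen response, steroid receptors and coregulators, arginine methylation, RGG motif RNA-binding proteins, DNA replication, mitosis, G1 regulators, p53 targets, interferon response, stress and unfolded protein response, cholesterol synthesis, fatty acid synthesis, immediate early genes, EGFR family and ligands, migration and adhesion, luminal genes, basal and squamous genes, hypoxia and glycolysis, ion and nutrient transport, heat shock, ribosomal proteins, markers of stroma and leukocytes, markers of other breast cell lines, and mitochondrially encoded and nuclear RNA. Some genes are in more than 1 list. Each list was tested in 5 comparisons with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 125 tests. The tests were repeated with a correlation estimated from the data and with fry. Of the 37 calls made at the preset correlation, 4 also held with an estimated correlation: progestin targets and hypoxia genes, each in both R5020 comparisons.

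Named genes follow a rule fixed before the data were examined. It takes PRMT1, PGR and ESR1 in each comparison. It adds the 8 highest and 8 lowest called fold changes for R5020 in siCT cells and for siPRMT1 in ethanol, and the 5 highest and 5 lowest for the other comparisons, among genes with a mean of at least 5 CPM and no overlap between the groups' libraries (a condition not applied to the interaction). It passes over clone names, and it adds up to 4 members per list and comparison with the smallest adjusted p. Some genes that the rule names are not reported here. A fold against a group with 0 counts was computed against a floor of 3 counts per library and is given as a lower bound. A ratio against a group with 1 to 3 counts is given with its exact Clopper-Pearson 95% counting interval.

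Simulated counts with 200 changed genes, drawn from the real means and library sizes, tested the procedure. With one spread for all libraries, 48% of 2-fold changes and 94% of 3-fold changes were recovered for R5020 in siCT cells, with 10 false calls among 131. In siPRMT1 cells 60% and 90% were recovered, for siPRMT1 in ethanol 56% and 92%, and for the interaction 10% and 54%. With the larger spread seen among the siCT libraries, the test of R5020 in siCT cells gave 127 false calls among 258, so its error rate was then not held at the nominal level. The same simulation gave 0 false calls among 121 for R5020 in siPRMT1 cells, 6 among 135 for siPRMT1 in ethanol and 5 among 80 for the interaction. Genes were drawn independently, whereas a pair of the real siCT libraries deviated in the same genes (r = 0.808 across genes). The simulated rates therefore need not hold for the real libraries.

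Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE size factors, library totals without further scaling, no filter and a stricter filter on low counts (at least 1 CPM in 6 libraries), a fit of only the groups compared, a replicate block, stricter thresholds (an adjusted p under 0.01, or a change of at least 2-fold) and leaving out each library in turn. A further 3 were chosen after seeing the data: leaving out both siCT libraries with a high mitochondrial share, limma-voom with sample quality weights, and leaving out mitochondrially encoded genes. GC content and transcript length came from GENCODE transcripts matched by symbol, which gave values for 14264 of the 17727 tested genes (80.5%). The coordinates of genes were not used here, and no library was left out of the main comparisons. Figures were drawn with matplotlib 3.10.9.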

Results

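Gene expression was measured in T47D breast cancer cells to ask whether PRMT1, a protein arginine methyltransferase, is needed for the response of genes to progestin. The 12 libraries fall into 4 groups of 3: siCT with ethanol, siCT with R5020, siPRMT1 with ethanol and siPRMT1 with R5020. Total counts ranged from 26783525 to 34120937 per library, and 17727 genes were tested.

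PRMT1 mRNA was lower in all 6 siPRMT1 libraries than in all 6 siCT libraries. It stood at 37.5 ± 7.83 CPM in siCT ethanol, 43.0 ± 6.89 in siCT R5020, 8.23 ± 0.268 in siPRMT1 ethanol and 7.08 ± 0.258 in siPRMT1 R5020 (SD, n = 3). PRMT1 fell 4.56-fold with siPRMT1 in ethanol (log2 fold change -2.19 ± 0.17 SE, adjusted p = 7.79e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and 6.07-fold in R5020 (adjusted p = 2.96e-06). R5020 itself gave no called change of PRMT1 with siCT (adjusted p = 0.532) or siPRMT1 (adjusted p = 0.507).

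A pair of siCT libraries stood apart from the rest. Mitochondrially encoded genes took 59.3% of counts in siCT ethanol replicate 3 and 52.4% in siCT R5020 replicate 1, against 31.3% to 38.3% in the other 10 libraries. The nuclear RNA MALAT1 stood at 1519 and 948 CPM in this pair and at 250.7 to 486.1 CPM in the others. The spread between replicates, as edgeR's common biological coefficient of variation, was 0.326 in siCT ethanol and 0.213 in siCT R5020, against 0.0462 in siPRMT1 ethanol and 0.0753 in siPRMT1 R5020. The list of mitochondrially encoded and nuclear RNA was not called by camera at its preset correlation in any comparison over all 12 libraries. In the interaction its median was 0.435 (adjusted p = 0.162), and camera called it with quality weights (median 0.366, adjusted p = 0.00531), without the pair (0.226, adjusted p = 0.0136) and with library totals alone (0.181, adjusted p = 0.0249). It was also called with siPRMT1 in ethanol with library totals alone (adjusted p = 0.0373). With siPRMT1 in ethanol its median was -0.914 (log2), with 0 of 13 members up and 2 down (0 and 0 adjusted over the list alone), among them MT-ATP6 at -1.39 and RN7SK at -1.91. That median was -0.523 with library totals alone. In siCT ethanol replicate 3 the list lay above the other libraries of its group by a median of 1.68.

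**Figure D1:**
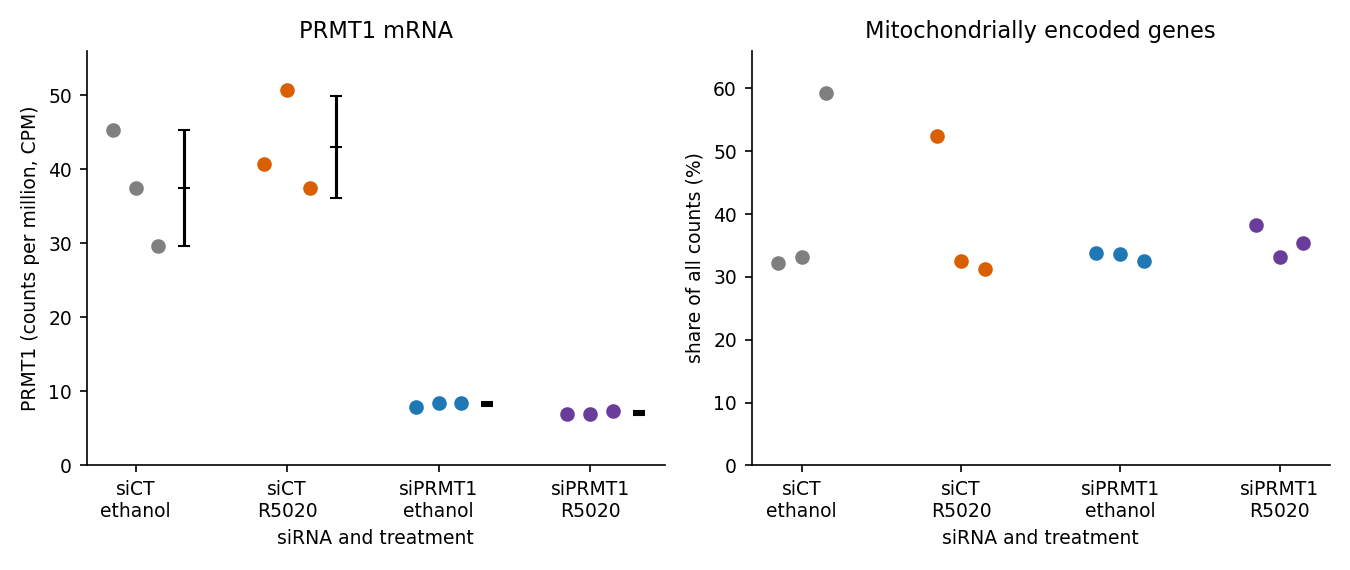
PRMT1 mRNA in CPM (left, with the mean and SD of each group beside its 3 libraries) and the share of counts from mitochondrially encoded genes in percent (right), by siRNA and treatment, 1 point per library. PRMT1 lay between 29.7 and 50.7 CPM with siCT and between 6.89 and 8.38 CPM with siPRMT1, and 2 siCT libraries had mitochondrial shares of 59.3% and 52.4%.

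The first comparison describes the progestin response in cells with normal PRMT1. In siCT cells R5020 raised SGK1, a glucocorticoid- and progestin-induced kinase, 89.6-fold (log2 6.49 ± 0.21, adjusted p = 1.46e-09). G6PC, the catalytic subunit of glucose-6-phosphatase, had 0 counts in ethanol and was at least 85.0-fold higher with R5020 (9.47 CPM against a floor of 0.111 CPM). Other strong increases were ZBTB7C, 33.5-fold (log2 5.07 ± 0.18), GPR124, 19.0-fold (log2 4.25 ± 0.25), HSD11B2, the enzyme that inactivates cortisol, 16.6-fold (log2 4.05 ± 0.30), SEC14L2, 16.2-fold, ALPL, an alkaline phosphatase, 15.2-fold, and PLLP (log2 3.91 ± 0.24). AMIGO2, a cell adhesion protein, fell 22.0-fold (log2 -4.46 ± 0.25), PCED1B 10.9-fold, the interleukin-1 receptor gene IL1R1 7.67-fold (log2 -2.94 ± 0.16), MECOM 6.17-fold, MKX 5.68-fold and TNFRSF11A, the RANK receptor, 5.41-fold, and TTC6 fell as well (log2 -2.48 ± 0.26). The antisense gene DSCAM-AS1 fell 5.65-fold, with reads that may include its partner since no strand setting is given. The receptor genes fell too: PGR 3.06-fold (log2 -1.61 ± 0.20, from 517 ± 127 to 169 ± 30.7 CPM) and ESR1 1.68-fold (log2 -0.75 ± 0.13).

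Progestin targets led the lists in siCT cells, with 20 of 28 tested members up and 1 down (22 and 1 adjusted over the list alone), a median log2 change of 1.53 and a camera adjusted p of 7.37e-45 (adjusted p = 2.07e-05 with an estimated correlation). Examples were the transcription factor STAT5A, 10.9-fold (log2 3.45 ± 0.16), S100P, 10.8-fold, and PDK4, which restrains pyruvate oxidation, 8.71-fold. ZBTB16, another target, had 0 counts in ethanol and was at least 13.8-fold higher. Hypoxia and glycolysis genes rose in 8 of 17 with none down (8 and 0 adjusted over the list alone; adjusted p = 7.07e-06, and adjusted p = 0.0272 with an estimated correlation), among them PFKFB3, 3.97-fold, HK2, 2.22-fold, BNIP3, 2.70-fold, and NDRG1, 2.89-fold.

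DNA replication genes were called up in 20 of 30 and down in 0 (25 and 0 adjusted over the list alone), with a median of 0.813, adjusted p = 8.21e-18 by camera and adjusted p = 0.268 with an estimated correlation. With library totals alone 10 rose and 0 fell by edgeR. GINS2, part of the replicative helicase, rose 6.57-fold (log2 2.71 ± 0.25), E2F1 2.87-fold, MCM5 2.81-fold and the polymerase subunit gene POLE2 2.49-fold. Of the G1 regulators 4 of 17 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.00285, and adjusted p = 0.576 with an estimated correlation). The cyclin gene CCND1 rose 3.01-fold, MYC 1.59-fold and the kinase inhibitor CDKN1C 8.27-fold, while the inhibitor CDKN2B fell 1.85-fold. The EGFR family and ligands rose in 6 of 16 with none down (7 and 3 adjusted over the list alone; adjusted p = 0.00117, and adjusted p = 0.777 with an estimated correlation), including the ligands EGF, 4.64-fold, and TGFA, 3.08-fold, and the feedback inhibitor ERRFI1, 4.42-fold. Immediate early genes went up in 6 of 20 and down in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.00168, and adjusted p = 0.824 with an estimated correlation): KLF4 rose 3.00-fold, FOSL2 2.22-fold and the phosphatase gene DUSP1 2.87-fold, and EGR1 fell 2.27-fold.

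Other lists were called in siCT cells as well. Heat shock genes rose in 6 of 16 (7 adjusted over the list alone; adjusted p = 0.00221, and adjusted p = 0.824 with an estimated correlation), with DNAJB1 2.27-fold and BAG3 1.99-fold higher; with library totals alone 0 rose and 0 fell by edgeR, with a median of 0.434 against 0.488. Ion and nutrient transport genes rose in 5 of 16 and fell in 1 (6 and 2 adjusted over the list alone; adjusted p = 0.00641, and adjusted p = 0.860 with an estimated correlation). The sodium channel gene SCNN1G rose 14.1-fold and ATP1B1 4.06-fold, and the amino acid transporter SLC6A14 fell 7.49-fold. This list lay higher by a median of 1.02 in siCT ethanol replicate 3 and 0.703 in siCT R5020 replicate 1, and without this pair its median was 0.614 against 0.399, with 9 up and 1 down. Fatty acid and lipid genes rose in 5 of 16 and fell in 1 (6 and 1 adjusted over the list alone; adjusted p = 0.0165, and adjusted p = 0.777 with an estimated correlation), with PLIN2 2.84-fold and FASN 2.04-fold higher and GPAM 1.93-fold lower. Interferon response genes fell in 8 of 28 and rose in 1 (12 and 1 adjusted over the list alone; adjusted p = 0.00221, and adjusted p = 0.576 with an estimated correlation): IFI44L fell 2.62-fold and IFIT2 1.67-fold, and HERC5 rose 2.27-fold. With library totals alone 2 interferon genes fell and 1 rose. Steroid receptors and coregulators fell in 5 of 22 and rose in 1 (9 and 2 adjusted over the list alone; adjusted p = 0.0253, and adjusted p = 0.842 with an estimated correlation): the pioneer factor gene FOXA1 fell 2.25-fold, while the coregulator GREB1 rose 5.16-fold. This list was not called by camera with library totals alone (adjusted p = 0.321, 3 down and 1 up).

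In all, 1345 genes rose and 963 fell with R5020 in siCT cells, and 4487 had an unadjusted p under 0.05. A fit of only these 6 libraries called 898 genes and a fit without the pair that stood apart called 3568. In simulations with the larger spread of the siCT libraries this test gave 127 false calls among 258, so the share of false calls was not held at its nominal level there.

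The same treatment was then compared in PRMT1-depleted cells. R5020 raised SGK1 53.7-fold (log2 5.75 ± 0.20), ALPL 51.8-fold (log2 5.70 ± 0.33), SEC14L2 32.2-fold (log2 5.01 ± 0.26) and the tissue factor gene F3 31.5-fold (log2 4.98 ± 0.29). G6PC rose from 1 count over the ethanol libraries to 1201 counts, a ratio of 1480 with a counting interval of 265 to 58400. AMIGO2 fell 13.8-fold (log2 -3.79 ± 0.24), MECOM 7.24-fold, the oncogene MYB 6.58-fold (log2 -2.72 ± 0.15), VAV3 6.35-fold and the kinase gene NUAK2 6.19-fold. PGR fell 4.10-fold (log2 -2.04 ± 0.20, from 1129 ± 20.7 to 275 ± 8.69 CPM) and ESR1 2.65-fold (log2 -1.40 ± 0.13).

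With siPRMT1, progestin targets rose in 22 of 28 and fell in 1 (22 and 1 adjusted over the list alone), with a median of 1.59, adjusted p = 5.90e-40 by camera and adjusted p = 2.07e-05 with an estimated correlation. STAT5A rose 11.2-fold, and ZBTB16 was at least 12.3-fold above 0 counts in ethanol. Hypoxia and glycolysis genes rose in 7 of 17 (12 adjusted over the list alone; adjusted p = 2.54e-07, and adjusted p = 0.0205 with an estimated correlation), with PFKFB3 6.32-fold and PFKFB4 2.84-fold higher. The EGFR list rose in 8 of 16 (9 up and 3 down adjusted over the list alone; adjusted p = 0.0172, and adjusted p = 0.842 with an estimated correlation), and EGFR itself rose 4.75-fold. NRG2, a ligand gene of the same list, went from 1 to 26 counts, a ratio of 32 with a counting interval of 5.26 to 1310. In this list 6 rose and 5 fell with library totals alone, 9 and 5 without the pair of libraries that stood apart, and 10 and 5 with quality weights, where camera did not call it (adjusted p = 0.0674). DNA replication genes rose in 8 of 30 and fell in 0 (10 and 0 adjusted over the list alone; adjusted p = 0.00218, and adjusted p = 0.827 with an estimated correlation), with GINS2 5.68-fold, POLE2 2.08-fold and the cyclin gene CCNE2 2.06-fold higher. Only 1 of the 30 rose with library totals alone, with a median of 0.223 against 0.399.

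G1 regulators rose in 4 of 17 and fell in 1 after siPRMT1 (4 and 1 adjusted over the list alone; adjusted p = 0.0270, and adjusted p = 0.777 with an estimated correlation); CCND1 rose 3.01-fold, CDKN1C 3.12-fold and the inhibitor CDKN1A 2.24-fold. The G1 list had a median of 0.228, and with library totals alone 0.0532, where camera did not call it (adjusted p = 0.151). Immediate early genes rose in 6 of 20 and fell in 2 (6 and 2 adjusted over the list alone; adjusted p = 0.0107, and adjusted p = 0.860 with an estimated correlation), with KLF4 4.16-fold and ZFP36 3.05-fold higher and EGR1 2.53-fold lower. The median was 0.338, and 0.167 with library totals alone. Steroid receptors and coregulators fell in 9 of 22 and rose in 1 (10 and 1 adjusted over the list alone; adjusted p = 7.65e-05, and adjusted p = 0.644 with an estimated correlation), including FOXA1, 3.85-fold. Luminal epithelial genes fell in 6 of 22 with none up (6 and 0 adjusted over the list alone; adjusted p = 0.00200, and adjusted p = 0.177 with an estimated correlation), among them the ETS factors EHF, 1.96-fold, and ELF5, 1.89-fold. Estrogen response genes fell in 6 of 22 and rose in 3 (8 and 3 adjusted over the list alone; adjusted p = 0.0107, and adjusted p = 0.777 with an estimated correlation), with GREB1 3.26-fold higher. With quality weights camera did not call this list (adjusted p = 0.0557, 11 down and 6 up).

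A total of 1648 genes rose and 1077 fell with R5020 in siPRMT1 cells. With library totals alone the split was 897 up and 1167 down, and the median of all genes moved by -0.172 (log2), so small changes depend on the scaling. A fit of only these 6 libraries called 7813 genes and a fit without the pair that stood apart called 5226.

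The question of the study is whether the progestin response itself differs after PRMT1 depletion, which the interaction tests. Of the 17727 genes 14 were called, 8 with a higher and 6 with a lower R5020 effect in siPRMT1 cells, and 720 had an unadjusted p under 0.05. MYB fell 1.98-fold with R5020 in siCT cells and 6.58-fold in siPRMT1 cells (interaction log2 -1.73 ± 0.21, adjusted p = 0.0203 by edgeR's quasi-likelihood test). KITLG, the KIT receptor ligand, fell 1.78-fold and 5.71-fold (interaction -1.68 ± 0.25, adjusted p = 0.0249). The transcription factor genes ZBTB7C and SOX4 rose by a smaller fold after depletion. ZBTB7C rose 33.5-fold and 10.3-fold (interaction -1.70 ± 0.23, adjusted p = 0.0243 by edgeR), and SOX4 4.37-fold and 1.93-fold (interaction -1.18 ± 0.17, adjusted p = 0.0249 by edgeR). MTSS1, an actin-binding protein, rose 2.73-fold and 8.30-fold (interaction 1.61 ± 0.26, adjusted p = 0.0447). The desmosomal gene PKP2 rose 2.38-fold in siPRMT1 cells and had a log2 change of -0.51 in siCT cells that was not called (interaction 1.76 ± 0.24, adjusted p = 0.0243).

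The starting level differed for several of these genes. In ethanol MYB stood at 4.40 CPM with siCT and 14.2 CPM with siPRMT1, and with R5020 at 2.22 and 2.15 CPM. KITLG stood at 14.6 and 35.8 CPM in ethanol and at 8.19 and 6.26 CPM with R5020. MTSS1 stood at 6.57 and 2.54 CPM in ethanol and at 17.9 and 21.1 CPM with R5020. PKP2 stood at 25.7 and 24.9 CPM in ethanol and at 18.1 and 59.1 CPM with R5020. Of the genes with a higher interaction 7 of 8 fell with siPRMT1 in ethanol (1.534 for independent lists). Of those with a lower one 6 of 6 rose (0.8147), ZBTB7C and SOX4 among them. The smaller R5020 folds of ZBTB7C and SOX4 thus started from higher ethanol levels. The interaction and siPRMT1 in ethanol both use the ethanol libraries, with opposite sign, so such an overlap arises in part without any effect. The interaction was not called for PGR (log2 -0.43 ± 0.28), ESR1 (-0.65 ± 0.18) or SGK1 (-0.74 ± 0.29). For the list of progestin targets it had a median of -0.123, with 0 of 28 members called by edgeR. Neither camera (adjusted p = 0.729) nor limma's fry (adjusted p = 0.927) called that list. The absence of a call does not show that the responses are equal.

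Among the lists, DNA replication genes had the clearest interaction, with a median of -0.477 and 0 of 30 members called (0 up and 7 down adjusted over the list alone; camera adjusted p = 5.70e-21, and adjusted p = 0.234 with an estimated correlation). Their members E2F2 (-0.82 ± 0.23), MCM5 (-0.77 ± 0.23), E2F1 (-0.74 ± 0.23) and CHAF1A (-0.70 ± 0.19) did not pass alone. The estrogen response list (median -0.129, adjusted p = 0.000204, and adjusted p = 0.576 with an estimated correlation) held 1 called member, MYB, and 3 adjusted over the list alone. The lists of steroid receptors (median -0.178, adjusted p = 0.000378, and adjusted p = 0.715 with an estimated correlation), mitosis (-0.211, adjusted p = 0.000403, and adjusted p = 0.576 with an estimated correlation), interferon response (0.194, adjusted p = 0.00487, and adjusted p = 0.576 with an estimated correlation) and luminal genes (-0.1, adjusted p = 0.0144, and adjusted p = 0.324 with an estimated correlation) held 0 called members by edgeR. Adjusted over the list alone, 2 steroid receptor genes passed, both lower, and 0 genes of the other 3 lists. These medians depend on the scaling. With library totals alone they were -0.597 for DNA replication, -0.279 for the estrogen response, -0.311 for steroid receptors, -0.341 for mitosis, 0.0523 for the interferon response and -0.249 for luminal genes.

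The count of 14 moved with the setting: DESeq2 called 89, a fit without the pair of libraries that stood apart 140, and library totals alone 3. Leaving out siCT R5020 replicate 2 or 3, or any 1 of the 6 siPRMT1 libraries, left 0 calls by edgeR with 538 to 636 genes at an unadjusted p under 0.05, and leaving out siCT ethanol replicate 1 or 3 or siCT R5020 replicate 1 gave 6, 32 and 4.

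**Figure D2:**
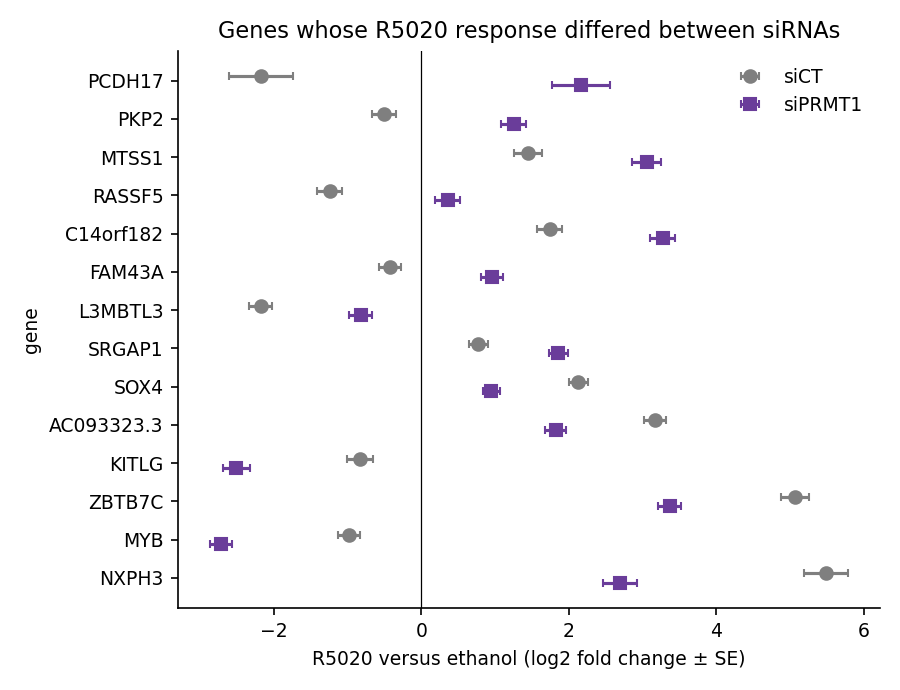
R5020 response (log2 fold change ± SE from the fit over 12 libraries, 3 per group) in siCT cells (circles) and siPRMT1 cells (squares) for the 14 genes called by the interaction. MYB changed by -0.98 and -2.72, and SOX4 by 2.13 and 0.95.

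The size of the response was compared over genes chosen by the average of both R5020 effects, which called 2343 genes up and 2135 down (1429 and 2233 with library totals alone). The spread was larger among siCT libraries, so this choice leans toward genes whose siCT change is large through that spread. The induced genes had a median log2 change of 0.781 in siCT and 0.869 in siPRMT1 cells, with a median interaction of 0.106. The repressed genes had medians of -0.697 and -0.716, with a median interaction of -0.0184. With library totals alone these median interactions were 0.00699 and -0.149. Neither set passed limma's fry test of a move one way. Over these genes the fold changes correlated with r = 0.918 and an orthogonal slope of 1.06 (genes are not independent replicates). Choosing genes by the average of both effects favours genes that change alike in both. A high r was therefore partly fixed in advance and does not show by itself that the responses are alike. The median interaction of induced genes turned to -0.0452 and -0.00947 without siCT ethanol replicates 1 and 3, and that of repressed genes to 0.109, 0.0282 and 0.0907 without siCT ethanol replicate 1 or 2 or siCT R5020 replicate 1.

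Calls with both siRNAs overlapped: 1081 genes rose in both, where independent lists would share 125, and 651 fell in both, where they would share 58.5. Only PCDH17, a gene with a low mean level of 0.346 CPM that was named after its values were seen, was called in opposite directions. Of the genes called in siCT cells alone (575) and in siPRMT1 cells alone (992), the interaction called 1 and 2. A call with a single siRNA thus does not by itself show a different response. Nor does it show an equal response, since the interaction recovered only 10% of 2-fold and 54% of 3-fold changes in the simulation with equal spread.

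**Figure D3:**
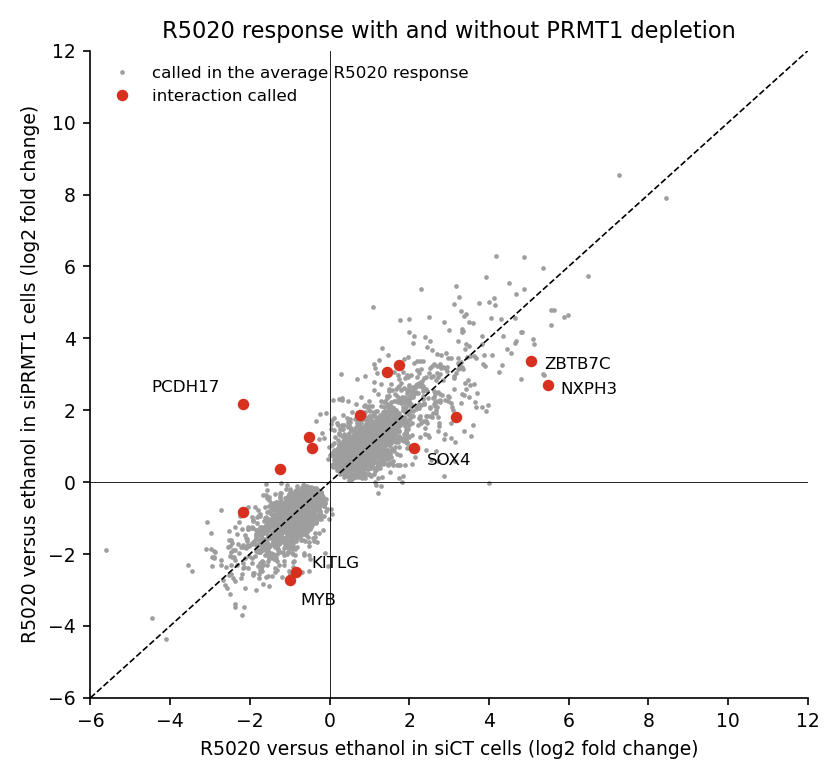
R5020 response in siCT cells (x axis) and siPRMT1 cells (y axis), both as log2 fold change, for 4454 genes called by the average response (grey; genes with a group at 0 CPM left out) and the 14 genes called by the interaction (red). The dashed line marks equal responses, and the correlation across all 4478 called genes was 0.918. These genes were chosen by the average of both effects, which by itself raises the correlation.

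The comparison of siPRMT1 with siCT without hormone was taken next. With a single siPRMT1 condition and a single control siRNA, effects of lower PRMT1 cannot be told apart from other effects of the siRNA. With siPRMT1 in ethanol the calcium-binding inflammatory genes S100A8 and S100A9 rose 20.3-fold (log2 4.34 ± 0.22, adjusted p = 5.09e-07) and 5.38-fold (log2 2.43 ± 0.22). SOWAHA rose 9.92-fold, CASP14, a caspase of cornifying skin, 8.23-fold (log2 3.04 ± 0.21), the RNA-binding pluripotency factor LIN28A 6.30-fold (log2 2.66 ± 0.17), STRIP2 5.74-fold, ZBTB7C 5.55-fold and ANKRD46 5.22-fold. The adhesion molecule MCAM fell 13.3-fold (log2 -3.74 ± 0.44), ADAMTSL4 9.65-fold, OLFML2A 8.41-fold, the extracellular superoxide dismutase SOD3 8.35-fold, CERCAM 8.04-fold, GLT8D2 7.86-fold, the phosphatase DUSP15 7.06-fold and EGR1 6.81-fold (log2 -2.77 ± 0.17, adjusted p = 2.22e-06). PGR rose 2.19-fold (log2 1.13 ± 0.20) and ESR1 2.26-fold (log2 1.17 ± 0.13).

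Several lists moved with siPRMT1 in ethanol. Migration, adhesion and mesenchymal genes fell in 11 of 23 and rose in 1 (13 and 1 adjusted over the list alone), with a median of -0.787, adjusted p = 0.00310 by camera and adjusted p = 0.820 with an estimated correlation. The integrin gene ITGA5 fell 4.89-fold (log2 -2.29 ± 0.34), CDH3 3.29-fold, and fibronectin (FN1) and CD44 each 2.79-fold. This list lay above the other siCT ethanol libraries by a median of 1.03 in siCT ethanol replicate 3, and without the pair of libraries that stood apart its median was -0.378, with 13 down and 2 up. It was -0.463 with library totals alone and -0.481 with quality weights. Immediate early genes fell in 12 of 20 and rose in 4 (12 and 4 adjusted over the list alone; adjusted p = 0.0257, and adjusted p = 0.872 with an estimated correlation). CTGF fell 17.5-fold, CYR61 5.56-fold and EGR1 as above, while IER3 rose 3.10-fold. Their median deviation in siCT ethanol replicate 3 was 0.581, and without the pair its median was -0.537 against -0.668, with 12 down and 6 up, and camera no longer called it (adjusted p = 0.0807).

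Steroid receptors and coregulators rose in 9 of 22 and fell in 2 (9 and 2 adjusted over the list alone; adjusted p = 0.00459, and adjusted p = 0.824 with an estimated correlation), with TFAP2C 1.89-fold and NCOA3 1.84-fold higher. The median deviation of this list in siCT ethanol replicate 3 was -0.317. Without the pair its median was 0.228 against 0.33, with 10 up and 3 down. Mitosis genes rose in 9 of 26 and fell in 1 (11 and 1 adjusted over the list alone; adjusted p = 0.00309, and adjusted p = 0.715 with an estimated correlation), among them TTK, 1.86-fold, BUB1, 1.78-fold, and CCNB1, 1.76-fold. Their median deviation in the same library was -0.36. Their median was 0.368 over all libraries and 0.351 without the pair, and with library totals alone 4 rose and 0 fell by edgeR. Heat shock genes rose in 5 of 16 (5 adjusted over the list alone; adjusted p = 0.00605, and adjusted p = 0.842 with an estimated correlation), with HSPH1 2.19-fold and HSP90AA1 1.83-fold higher. Their median deviation in siCT ethanol replicate 3 was -0.636, and without the pair their median was 0.207 against 0.377 and camera did not call the list (adjusted p = 0.0659). Of 4 stromal and leukocyte markers tested 2 fell (3 adjusted over the list alone; adjusted p = 0.00200, and adjusted p = 0.177 with an estimated correlation): the smooth muscle actin gene ACTA2, 6.43-fold, and LUM, 3.04-fold. Their median deviation in siCT ethanol replicate 3 was 1.28, and without the pair their median was -0.627 against -1.5 (adjusted p = 0.0243 by camera).

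The lists that follow were not called by camera at its preset correlation with siPRMT1 in ethanol over all libraries. By limma's fry the markers of other breast cell lines (adjusted p = 0.000282), basal and squamous genes (adjusted p = 0.00937) and p53 targets (adjusted p = 0.0225) were called, camera called ribosomal proteins with quality weights (adjusted p = 0.000677), and with library totals alone ion and nutrient transport (adjusted p = 0.0274). Interferon response genes rose in 6 of 28 and fell in 7 (6 and 10 adjusted over the list alone, camera adjusted p = 0.935). OASL rose 3.00-fold and IFIT2 rose (log2 1.32 ± 0.155), and MX1 fell 1.84-fold. With library totals alone 6 interferon genes rose and 1 fell by edgeR, so the balance depends on the scaling. Arginine methylation genes rose in 2 of 18 and fell in 5 (2 and 5 adjusted over the list alone, camera adjusted p = 0.387). Their median was 0.174 and their mean -0.177, with a test pointing down. BTG2, a binding partner of PRMT1, was 3.29-fold, the PRMT5 partner WDR77 2.28-fold and PRMT2 1.93-fold lower. With library totals alone the median of this list was 0.313, with 1 up and 3 down. The p53 targets (4 up and 6 down of 20, the same adjusted over the list alone; adjusted p = 0.557) held RRM2B, 2.23-fold higher, and BBC3, 1.93-fold lower. Basal and squamous genes (2 up and 3 down of 15, the same adjusted over the list alone; adjusted p = 0.225) held S100A8 and S100A9 on the one side and KRT81, 8.61-fold lower, on the other. RGG motif RNA-binding proteins rose in 3 of 26 (2 adjusted over the list alone, camera adjusted p = 0.291). Cholesterol genes rose in 1 of 19 and fell in 4 (2 and 5 adjusted over the list alone, camera adjusted p = 0.676), with HMGCS1 2.48-fold higher and CYP51A1 2.48-fold lower. Stress and unfolded protein response genes rose in 1 of 20 and fell in 1 (1 and 1 adjusted over the list alone), PSAT1 rising by a log2 change of 1.11. Camera did not call the stress list (adjusted p = 0.925), with a median of -0.168 and a test pointing up. Its median turned to 0.00978 with library totals alone. Ribosomal protein genes fell in 3 of 34 (0 adjusted over the list alone; adjusted p = 0.201), with a median deviation of -0.774 in siCT ethanol replicate 3; without the pair 27 fell, with a median of -0.494 against -0.338, and camera called the list (adjusted p = 9.17e-06). Markers of other breast cell lines rose in 1 of 9 and fell in 3 (1 and 3 adjusted over the list alone; adjusted p = 0.158), including PTRF, 6.03-fold lower. Without the pair camera also called these markers (median -0.246, adjusted p = 0.0340), ion and nutrient transport (0.492, adjusted p = 0.00226) and the estrogen response (0.33, adjusted p = 0.0108).

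In total 2407 genes rose and 3399 fell with siPRMT1 in ethanol, and of the changes of at least 2-fold 701 were up and 1873 down. The count was 3324 with only these groups fitted and 3021 with library totals alone (1325 up and 1696 down, with the median of all genes moved by 0.176), and it was 3655, 3775 and 3487 without siPRMT1 ethanol replicates 1, 2 and 3.

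**Figure D4:**
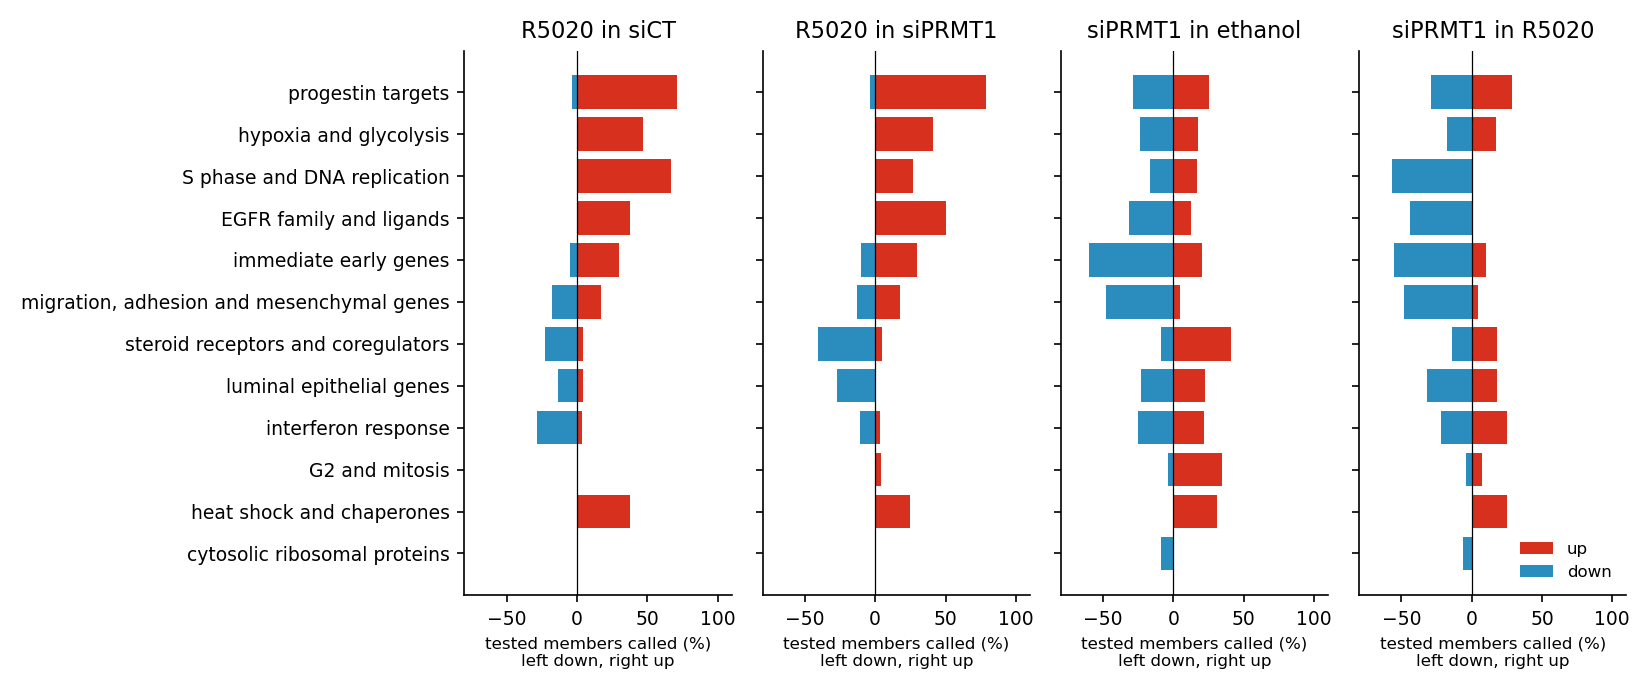
Share of the tested members of 12 gene lists that were called up (to the right) or down (to the left), in percent, in the R5020 and siPRMT1 comparisons. DNA replication genes were called up in 20 of 30 with R5020 in siCT cells and down in 17 of 30 with siPRMT1 in R5020.

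With hormone present, siPRMT1 raised S100A8 18.6-fold (log2 4.21 ± 0.22), CASP14 12.2-fold (log2 3.61 ± 0.22), the cytoskeletal linker EPB41L3 8.06-fold, ANKRD46 6.43-fold and S100A9 6.01-fold. MCAM fell 9.35-fold (log2 -3.22 ± 0.44), EGR1 7.60-fold (log2 -2.93 ± 0.18), the microtubule-associated gene MAP1A 7.13-fold, FOSB 6.95-fold and CERCAM 6.66-fold. PGR rose 1.63-fold and ESR1 1.44-fold. DNA replication genes fell in 17 of 30 with none up (17 and 0 adjusted over the list alone), with a median of -0.626, adjusted p = 6.03e-06 by camera and adjusted p = 0.715 with an estimated correlation. Of these 30 genes 3 fell and 0 rose by edgeR with library totals alone, with a median of -0.611. E2F1 fell 2.47-fold, DTL 1.97-fold and MCM5 1.93-fold, and CDC6 fell too (log2 -1.14 ± 0.15).

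Immediate early genes fell in 11 of 20 and rose in 2 with siPRMT1 in R5020 (11 and 4 adjusted over the list alone; adjusted p = 0.00328, and adjusted p = 0.842 with an estimated correlation), with IER2 2.47-fold and DUSP1 2.27-fold lower. Their median deviation in siCT R5020 replicate 1 was 0.369. Without the pair of libraries that stood apart their median was -0.598 against -0.69, with 11 down and 6 up. Migration and adhesion genes fell in 11 of 23 and rose in 1 (12 and 1 adjusted over the list alone; adjusted p = 0.00618, and adjusted p = 0.824 with an estimated correlation), with ITGA5 3.81-fold, CDH3 3.24-fold and FN1 2.75-fold lower. This list lay above the other siCT R5020 libraries by a median of 0.583 in siCT R5020 replicate 1, and without the pair its median was -0.509 against -0.791, with 13 down and 3 up (adjusted p = 0.00202 by camera). Basal and squamous genes rose in 4 of 15 and fell in 4 (4 and 4 adjusted over the list alone; adjusted p = 0.0184, and adjusted p = 0.324 with an estimated correlation), S100A2 falling 3.68-fold, and the stromal markers fell in 2 of 4 (2 adjusted over the list alone; adjusted p = 0.0178, and adjusted p = 0.324 with an estimated correlation), ACTA2 by 5.57-fold. Without the pair of libraries that stood apart the basal and stromal lists were not called by camera (adjusted p = 0.0912 and 0.108), nor with quality weights (adjusted p = 0.561 and 0.374), and the stromal median was 0.09 against -0.843. The stromal markers were not called by camera with library totals alone either (adjusted p = 0.138). Ribosomal protein genes were not called by camera at its preset correlation over all libraries (adjusted p = 0.235), but were called without the pair (median -0.346, 19 down and 1 up, adjusted p = 0.00116) and with quality weights (23 down and 2 up, adjusted p = 0.000475). Markers of other breast cell lines were likewise called by camera without the pair (median -0.372, adjusted p = 0.0243) and not over all libraries (adjusted p = 0.172), where limma's fry called them (adjusted p = 0.000684). Interferon genes rose in 7 of 28 and fell in 6 (8 and 6 adjusted over the list alone). Camera did not call them (adjusted p = 0.271), with a median of -0.151, a mean of 0.114 and a test pointing up. OASL was 3.70-fold, IFIT2 2.67-fold and IFIT3 2.62-fold higher. With library totals alone 6 interferon genes rose and 1 fell by edgeR.

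A total of 2046 genes rose and 2513 fell with siPRMT1 in R5020, and with library totals alone 744 rose and 1685 fell. Without siPRMT1 R5020 replicates 1, 2 and 3 the counts were 2892, 2332 and 2654, and without the pair of siCT libraries that stood apart 6992. Of the genes called in both treatments 1568 rose in both (independent lists would share 277.8) and 2059 fell in both (481.8).

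Genes that responded to R5020 and to siPRMT1 were compared with the shared siCT ethanol libraries in mind. R5020 in siCT cells and siPRMT1 in ethanol shared 259 genes up in both (182.6 for independent lists) and 293 down in both (184.6), while 240 rose with R5020 and fell with siPRMT1 (257.9) and 154 did the opposite (130.8). The fold changes correlated across genes with r = 0.111 and a covariance of 0.0627. In 10 simulations all groups were drawn from the siCT ethanol means with no gene changed. The mean r was then 0.650 and the mean covariance 0.0689 (0.0667 to 0.0706). The observed covariance lay below this range, so it shows no shared response beyond what shared controls give. The simulations gave 0 shared calls, but with no changed genes this was nearly fixed in advance and cannot be set against the observed overlap. The 3 control libraries are too few to split, so part or all of the excess in shared calls may come from the shared controls.

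The authors' deposited table, at an adjusted p under 0.05, lists 881 genes up and 402 down for R5020 in siCT cells, 3691 and 2972 for R5020 in siPRMT1 cells, 1819 and 2262 for siPRMT1 in ethanol, and 2958 and 2964 for siPRMT1 in R5020. Of the edgeR calls made here, 54.8%, 98.0%, 67.9% and 93.4% were called in the same direction in the authors' deposited table, and 0 were called in opposite directions. Among the 17702 genes found in both tables, and in the same order, 100%, 40.6%, 98.8% and 72.6% of the calls in the authors' deposited table were called here. The log2 fold changes of the authors' deposited table and those computed here correlated across genes with r from 0.962 to 0.982.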

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

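The tests chosen only after the result was seen are those of mitochondrial counts alone, of the libraries with a high mitochondrial share (for the falls and for the replication genes) and of cytosolic RNA (both), together with the reading of the permutation of replication genes, the bootstrap interval of the marker median and the fits without both libraries and with quality weights.

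The R5020 effect differed between siCT and siPRMT1 cells for 14 genes by the interaction. It was higher in siPRMT1 cells for PCDH17 (4.34, log2), PKP2 (1.76), MTSS1 (1.61), RASSF5 (1.6), C14orf182 (1.53), FAM43A (1.38), L3MBTL3 (1.36) and SRGAP1 (1.09). It was lower for NXPH3 (-2.8), MYB (-1.73), ZBTB7C (-1.7), KITLG (-1.68), AC093323.3 (-1.34) and SOX4 (-1.18). PCDH17, C14orf182, SRGAP1, NXPH3 and AC093323.3 lie outside the rule for named genes and were chosen after their values were seen. PCDH17 had a mean of only 0.346 CPM over all libraries, NXPH3 2.64 and C14orf182 3.82, all under the 5 CPM of that rule. All 14 were also called by DESeq2 and without both siCT libraries with a high mitochondrial share, and 11 of 14 with quality weights. As above, 0 genes were called by edgeR without siCT R5020 replicate 2 or 3, or without any 1 siPRMT1 library, so single genes in this set need a repeat.

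The interaction also differed for 6 gene lists by camera at its preset correlation, with medians of -0.477 for DNA replication, -0.211 for mitosis, -0.178 for steroid receptors and coregulators, -0.129 for the estrogen response, -0.1 for luminal genes and 0.194 for the interferon response. With an estimated correlation none of these 6 was called, and by fry only the replication genes were (adjusted p = 0.0433 by limma's fry).

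A pair of siCT libraries stood apart: ethanol replicate 3 and R5020 replicate 1 deviated from the other libraries of their groups in the same genes (r = 0.808 across genes, which are not independent replicates). Without mitochondrially encoded genes the lower of their deviations (SD across genes) was 1.03 times the highest of the other libraries, since siCT ethanol replicates 1 and 2 also differed from each other, so that value does not separate the pair. Mitochondrial counts alone would leave nuclear genes in proportion, and the shift between families of nuclear genes given next argues against them, as does 2.91% of the variance at most against a trend with GC content or transcript length. RNA of mesenchymal breast cells stays open: the medians of 9 markers were -0.152 and -0.358, but their bootstrap intervals (-0.666 to 1.1 and -0.513 to 0.583) are wide, with FN1 higher (0.798 and 0.583) and LGALS1 lower (-0.471 and -0.358). A loss of cytosolic RNA, which would leave mitochondrial, nuclear and membrane-bound RNA, is a candidate explanation. Genes of membrane families lay above cytosolic ones by 1.47 (1.37 to 1.58) in ethanol replicate 3 and 0.908 (0.841 to 0.968) in R5020 replicate 1. These bootstrap intervals resample genes within a single library's deviation and measure no spread between libraries. The hypothesis came from the gene lists of the same libraries, and no biological explanation was tested.

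After siPRMT1 in ethanol 72.8% of changes of at least 2-fold were falls. Without both libraries with a high mitochondrial share 67.4% were falls (1552 against 750), which argues against them as the whole cause, and after a correction for GC content and length 66% were (1023 against 526, and 71.2% before it on the same 14264 genes), which argues against that trend as the whole cause. Over calls of any size falls were fewer in proportion: 3399 against 2407 rises over all libraries, 4375 against 3628 without the pair, and 2331 against 2151 after the correction (2713 against 2091 before it on the same genes). The difference between membrane and cytosolic families was -0.514 (-0.623 to -0.373, bootstrap over genes) over all libraries and -0.0862 (-0.213 to 0.0148) without the pair. A loss of cytosolic RNA in siCT libraries may thus account for part of the falls. The value without the pair argues against a loss of the same size in the siCT ethanol libraries left, though its interval does not cover the spread between libraries. This value describes these families and not the falling genes themselves, so a milder loss stays open. An effect of PRMT1 depletion itself stays open and was not tested apart from these.

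DNA replication genes had a median interaction of -0.477, with 0 of 30 members called by edgeR (7 lower adjusted over the list alone) and adjusted p = 0.234 by camera with an estimated correlation. The median was -0.396 without both libraries with a high mitochondrial share and -0.496 after the GC and length correction, which argues against either as the whole cause, and it ranged from -0.604 (without siCT ethanol replicate 1) to -0.427 (without siCT ethanol replicate 3). The spread between libraries stays open: the interaction of the mean list level was -0.5, with an exact permutation p of 0.075 (two-sided, over 400 regroupings), but 24 of the 30 regroupings as large as the real one keep or wholly exchange the siRNA groups of a treatment and so carry the siRNA effect, and this p decides nothing. The list of mitochondrially encoded and nuclear RNA moved the other way: its median was 0.435 over all libraries, where camera did not call it (adjusted p = 0.162), and 0.366 with quality weights, 0.226 without both libraries and 0.181 with library totals alone, where camera did (adjusted p = 0.00531, 0.0136 and 0.0249). A weaker progestin effect on replication genes in cells with less PRMT1 is therefore a hypothesis.

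Other splits of the same libraries were counted for each comparison. For R5020 in siCT cells 2 of 10 splits gave as many genes: 2308 for the real one and 2380 for the one that sets siCT ethanol replicates 1 and 3 and R5020 replicate 1, and so both libraries with a high mitochondrial share, against the rest. The split of siCT ethanol replicate 1 and R5020 replicates 2 and 3 against the rest also keeps both of these libraries on one side and gave 2110, and without that pair 3568 genes were called. For R5020 in siPRMT1 cells 1 of 10 splits gave as many (2725 against 0 for the highest other), for siPRMT1 in ethanol 1 of 10 (5806 against 0) and for siPRMT1 in R5020 1 of 10 (4559 against 0), the 0 counts being by edgeR. In each of these 4 comparisons 10 splits are too few for a share under 0.05. All other splits also mix the groups compared, so the effect itself enters the spread and few genes can be called. For the interaction 3 of 100 splits gave as many as 14, but this share decides nothing. Most other splits mix siCT and siPRMT1 libraries, so the siRNA effect enters the spread and few genes can be called. The splits with 8582 and 2171 calls wholly exchange the siRNA labels in R5020 and so measure the siRNA effect. For the average R5020 response 1 of 100 gave as many (4478 against 1324), and this share decides nothing either. Most other splits mix ethanol and R5020 libraries, so the R5020 effect enters the spread. The split with 1324 calls keeps the treatment labels whole in siPRMT1 cells.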

How the results depend on the processing

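The fits without both siCT libraries with a high mitochondrial share, with sample quality weights and without mitochondrially encoded genes were chosen after seeing the data.

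Of 355 named results that were called in the main fit, none turned sign under any alternative. Named results not called there were left out of this count. The 355 were mostly chosen for large changes or small p-values in these same libraries, which favours stable signs. All 355 kept their call with DESeq2 and without both libraries with a high mitochondrial share, 103 lost it with library totals alone, 13 without a filter, 8 with quality weights, 5 with RLE size factors, 36 of 343 with only the groups compared, and 36 to 42 without any 1 siPRMT1 library (4 to 25 without any 1 siCT library).

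Counts of called genes moved more. With at least a 2-fold change they were 1297 (R5020 in siCT), 1481 (R5020 in siPRMT1), 2574 (siPRMT1 in ethanol), 1989 (siPRMT1 in R5020) and 1500 (average R5020). At an adjusted p under 0.01 by edgeR they were 1337, 1649, 2794, 1922 and 2860 in the same order, 0 for the interaction and 1050 for genes shared by both R5020 comparisons; fewer genes pass a stricter threshold by construction. With library totals alone they were 3021 for siPRMT1 in ethanol, 2429 for siPRMT1 in R5020 and 3 for the interaction. With only the groups compared they were 898 for R5020 in siCT, 7813 for R5020 in siPRMT1 and 3324 for siPRMT1 in ethanol, and 5895 for siPRMT1 in R5020. Without both libraries they were 3568, 5226 and 6992 (R5020 in siCT, R5020 in siPRMT1, siPRMT1 in R5020), 140 for the interaction and 2899 for the shared genes. With quality weights they were 8179 for R5020 in siPRMT1, 9866 for siPRMT1 in R5020 and 65 for the interaction. The interaction gave 89 genes with DESeq2, holding all 14, and 29 without a filter, holding 13. Where no reason is given, the cause was not tested.

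Leaving out each library in turn gave 1550 to 3029 genes (R5020 in siCT), 1831 to 3820 (R5020 in siPRMT1), 3487 to 7827 (siPRMT1 in ethanol), 2332 to 6768 (siPRMT1 in R5020) and 3615 to 5462 (average R5020). The lowest for siPRMT1 in ethanol were 3655, 3775 and 3487 without siPRMT1 ethanol replicates 1, 2 and 3, and for siPRMT1 in R5020 2892, 2332 and 2654 without siPRMT1 R5020 replicates 1, 2 and 3. The interaction ranged from 0 to 32 by edgeR, with 6 and 32 without siCT ethanol replicates 1 and 3, 4 without siCT R5020 replicate 1, and 0 without siCT R5020 replicate 2 or 3 or any 1 siPRMT1 library (538 to 636 genes at an unadjusted p under 0.05; 89 by DESeq2 on all libraries). Of the 37 list calls by camera, 4 held with an estimated correlation, 22 were among the 32 made by fry, 34 among 42 with library totals alone, 33 among 50 without both libraries and 33 among 44 with quality weights.

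Replicate numbers do not pair the samples: libraries with the same number had a mean correlation of -0.0495 (-0.667 to 0.29) against 0.0296 for others, and 2 of 12 libraries correlated best with their own number. With the replicate number as a block the counts were 1890 for R5020 in siCT, 2278 in siPRMT1 and 0 for the interaction by edgeR (594 at an unadjusted p under 0.05), and 27 of 355 named results lost their call.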
